A study of Mus musculus with 12 samples.

How the data were processed

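Gene expression was measured by RNA sequencing in 12 mouse liver libraries. There were 4 wild-type livers, 4 livers of mice lacking E2f7 and E2f8 (DKO, double knockout) and 4 liver tumors of DKO mice. Per the labels, total RNA was isolated on spin columns, polyadenylated RNA was enriched in 2 steps, and libraries were read on a SOLiD instrument. The deposited values are RPKM, reads per kilobase of exon per M reads (M, mega) of the library. The authors' processing notes name BWA and the mouse build mm9 without versions or roles, and neither the counting tool nor a filter is given in the sources used here. Each file holds 1 library with 21247 RefSeq transcripts, each with a gene symbol, an exon length and mm9 coordinates. Whether the coordinates are counted from 0 or 1 is not stated.

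A value times its exon length was a whole multiple of 1 step per library for at least 99.99% of values, within a tolerance of 0.05 of a read. The depth and the reads per gene follow from that step. Depth ranged from 7.985 to 15.956 M reads, and 1 read in a transcript with 2 kb of exons corresponds to 0.0313 to 0.0626 RPKM. Reads carry no molecular identifiers, so depth describes counting error only.

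The files hold 19012 gene symbols, of which 1520 have more than 1 transcript. The transcript with the longest exon length was kept for each symbol. Accessions of 18503 symbols matched the current gene table, which was used for current names only. Animal codes in the names of the deposited data are shared by the DKO liver and the DKO tumor of the same replicate number, and the wild-type codes are of other animals. The names also carry the tag L02 for all DKO livers and wild-type livers 1 and 2, or L03 for all DKO tumors and wild-type livers 3 and 4. The tags are read here as sequencing lanes, which the labels do not state.

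The tests, groups, gene lists, named-gene rule and most alternatives were set before the data were examined. A count-based test had been planned first and was replaced, under a provision made at the same time, because the values are RPKM. Genes with at least 0.5 RPKM in at least 4 libraries were tested, 11351 in all. A linear model with a mean per group was fitted over the 12 libraries to log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance shrinkage. The test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The offset of 1 understates fold changes of genes with low values. DKO tumor and DKO liver were also compared over their 8 libraries with the animal as a block. Values per gene are mean RPKM ± SD with n = 4 libraries per group.

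The gene lists numbered 33, with 857 entries, of which 844 matched a symbol in the data. Some genes belong to several lists and are counted in each. They cover E2F targets and DNA replication, mitosis, p53 targets, liver cancer and fetal liver markers, hepatocyte proteins and functions, liver zonation, sex-biased genes, cell-type markers, and housekeeping and stress genes. Each list was tested against the other genes with camera from limma at a preset correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation. Named genes are E2f7 and E2f8, then the 8 largest rises and the 8 largest falls among changed genes whose groups did not overlap and whose higher mean was at least 5 RPKM. From each list described, up to 4 changed members with the smallest p-values were eligible, or the 2 members with the highest mean where none changed. The text names some of these. Genes chosen after their values were seen are identified as such.

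E2f7, E2f8 and the mean of each list per library were compared with two-sided exact permutation tests over 70 splits of 4 against 4 libraries, which cannot give p below 0.029. The fits were tested on simulated data of the same size in 5 runs. The 12-library model recovered 61.2 to 66.6% of planted 2-fold changes and at least 93.5% of 4-fold changes. The blocked model recovered 28.4 and 89.9%. A mean of 5.8 to 10 unchanged genes were called per simulated run. Changes were planted on the scale of the fit, after the offset, so genes with low values need larger changes in RPKM. Simulated genes varied independently and without a lane difference, so these shares do not give the power in the real libraries.

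Alternatives covered median-of-ratios scaling, quantile normalization, an offset of 0.1, no filter, a stricter filter and non-robust shrinkage. Others were the 8 libraries of a comparison alone, the lane tag as a covariate, replicate blocks, voom on the recovered reads, a random animal effect with statmod 1.5.0, another transcript per gene, and the Arntl level as a covariate. Further fits left out DKO animals 1 and 2, kept only 1 lane, or left out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the data, and matplotlib 3.10.9 drew the plots. Raw reads were not analysed here.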

Results

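RPKM was compared among 4 wild-type livers, 4 livers and 4 liver tumors of mice lacking E2f7 and E2f8, which encode the atypical, repressing members of the E2F family. Wild-type livers had 7.985, 12.809, 11.887 and 14.234 M reads (M, mega). DKO livers had 12.093, 10.034, 12.323 and 9.274 M, and DKO tumors had 15.956, 12.702, 14.298 and 15.026 M. Liver and tumor of the same replicate number share an animal code, whereas wild-type livers came from other animals.

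E2f7 lies on mm9 chromosome 10 from 110182520 to 110224439 and E2f8 on chromosome 7 from 56121833 to 56136369. E2f7 had 6, 8, 13 and 8 reads in the wild-type livers, 14, 22, 16 and 14 in the DKO livers, and 21, 18, 14 and 3 in the DKO tumors. Its mean was 0.138 ± 0.043 RPKM in wild-type livers, 0.281 ± 0.084 in DKO livers and 0.179 ± 0.101 in DKO tumors (n = 4 each). E2f8 was at 4.30, 1.66, 2.26 and 2.57 RPKM in the wild-type livers, 8.08, 20.76, 7.36 and 2.80 in the DKO livers, and 1.66, 12.24, 3.68 and 5.23 in the DKO tumors. For DKO liver against wild-type liver the exact permutation p was 0.0286 for E2f7 (log2 difference 0.17) and 0.0571 for E2f8 (1.32). For DKO tumor against DKO liver it was 0.2 for E2f7 (−0.12) and 0.4 for E2f8 (−0.65). For DKO tumor against wild-type liver the exact permutation p was 0.543 for E2f7 (0.05) and 0.286 for E2f8 (0.66). RPKM sums all exons of a transcript and the deleted part of each gene is not given in the sources used here, so these values do not check the genotype.

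**Figure D1:**
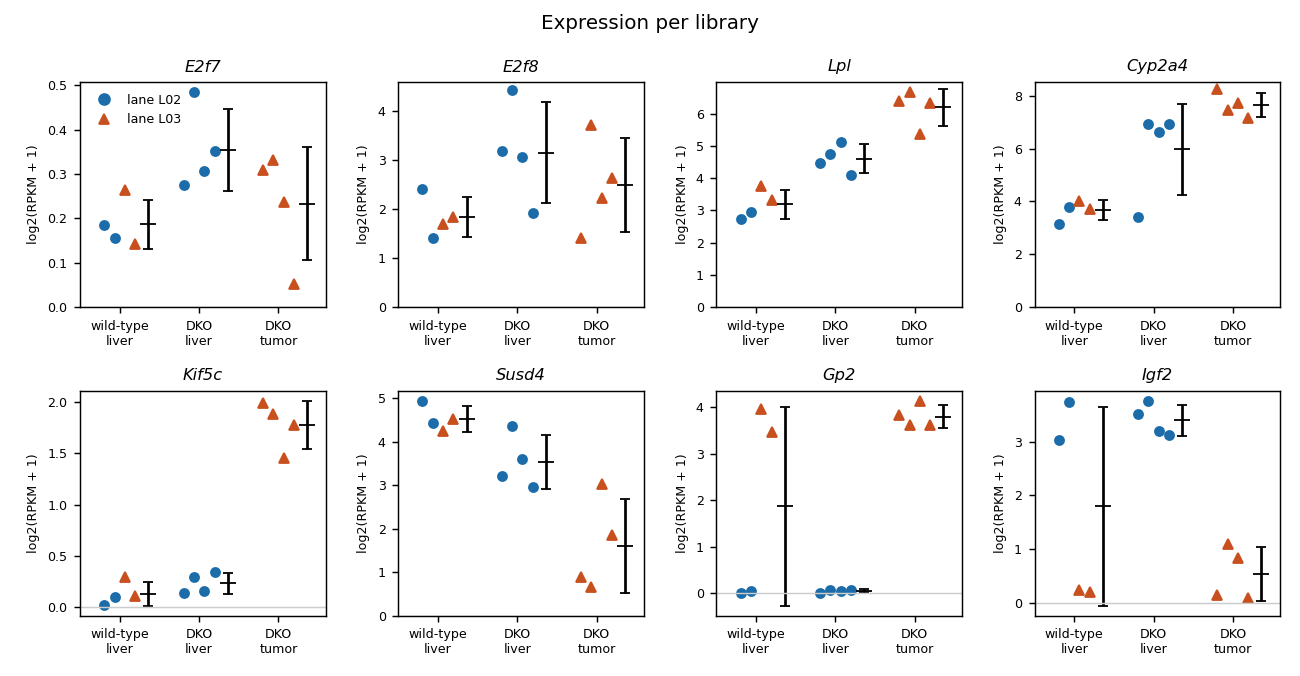
log2(RPKM + 1) of 8 genes in each of the 12 libraries, by group, with circles for libraries tagged L02, triangles for L03, and bars for the group mean ± SD (n = 4). Lpl was higher in all 4 DKO tumors than in all wild-type livers, while Gp2 and Igf2 also differed between the wild-type livers of the 2 tags.

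DKO tumors were compared with wild-type livers to find genes that differ between tumor tissue without E2f7 and E2f8 and normal liver. Lipoprotein lipase, encoded by Lpl (chromosome 8, 71404453 to 71430830), rose from 8.47 ± 3.07 to 76.1 ± 25.8 RPKM (n = 4 each; log2 change 3.0, SE 0.31, limma adjusted p = 9.85e-04). The basement membrane gene Nid1 rose from 4.02 ± 1.08 to 36.7 ± 18.0 (2.83, adjusted p = 0.0047), and the anti-proliferative p53 target Btg2 from 2.98 ± 1.16 to 18.9 ± 5.13 (2.33, adjusted p = 0.0052). Susd4, encoding a complement regulator (chromosome 1, 184695036 to 184825784), fell from 22.5 ± 5.13 to 2.82 ± 3.07 (−2.92, adjusted p = 0.0169). In all, 216 of 11351 genes changed, 140 up and 76 down.

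Other genes with large rises encode secreted, metabolic and endothelial products. Igfbp1, an insulin-like growth factor binding protein, rose from 17.1 ± 7.97 to 194 ± 130 RPKM (log2 change 3.30, limma adjusted p = 0.0178). Scd2, a desaturase, rose from 5.35 ± 2.61 to 64.4 ± 68.3 (2.90, adjusted p = 0.0296). The endothelial gene Esm1 rose from 0.598 ± 0.333 to 11.2 ± 3.73 (2.90, adjusted p = 0.0138), and Gldn from 0.708 ± 0.723 to 12.2 ± 6.80 (2.78, adjusted p = 0.0319). The interferon-related gene listed as 1810023F06Rik, now Ifi27l2b, rose from 5.34 ± 3.65 to 37.4 ± 5.51 (2.80, adjusted p = 0.0461). Among falls, the lipid transporter gene Mfsd2, now Mfsd2a, went from 26.6 ± 11.3 to 3.38 ± 4.06 (−2.94, adjusted p = 0.0215). The gene listed as 1100001G20Rik, now Wfdc21, fell from 721 ± 246 to 114 ± 84.9 (−2.94, adjusted p = 0.0319).

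Several further large changes are uncertain because reads can be shared with other genes. Cyp2a4 (chromosome 7, 27092210 to 27100106), nearly identical to Cyp2a5, went from 12 ± 3.10 to 209 ± 70.0 RPKM (log2 change 3.99, SE 0.65, limma adjusted p = 0.0181). The major urinary protein genes Mup5, Mup4, Mup1 and LOC620807 (now Mup6) are near-identical copies. Mup5 went from 435 ± 219 to 34.2 ± 31.4 (−3.82, adjusted p = 0.0215), and the log2 changes of LOC620807, Mup4 and Mup1 were −3.59, −3.30 and −3.28. Lrtm1 went from 23.8 ± 6.33 to 3.65 ± 3.36 (−2.73, adjusted p = 0.0297), but it lies inside Cacna2d3 on the opposite strand and the strand of the reads is not given in the sources used here.

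Within lane L03, where 4 tumors faced 2 wild-type livers, limma called 25 genes, 23 up and 2 down, and 24 of them were among the 216. With the lane as a covariate over 12 libraries, 3 genes passed: Lpl (2.66, adjusted p = 0.0321), Tubb2a (2.46, adjusted p = 0.0491) and Kif5c (1.57, adjusted p = 0.0088). Kif5c and Tubb2a, encoding a kinesin and a tubulin, were chosen after their values were seen. The median change of the 216 genes in the called direction was 1.18 (SE 0.24) without and 1.12 (SE 0.30) with the covariate. The number of changed genes was 21 without wild-type liver 1, 83 without wild-type liver 2 and 16 without wild-type liver 4. It was 37 without DKO tumor 1, 20 without DKO tumor 2 and 413 without DKO tumor 3. Of 33 named changed genes, Btg2, Lpl and Nid1 passed in every one of the 12 fits that left out 1 library. Groups did not overlap for 1349 genes (11.9%, where chance gives 2.9%).

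Mitotic and liver cancer lists were higher in DKO tumors than in wild-type livers. Among the 36 mitotic and G2/M genes, 35 had positive log2 changes (median 0.72). Kif2c, encoding a mitotic kinesin, rose from 0.194 ± 0.106 to 0.846 ± 0.266 RPKM (log2 change 0.62, limma adjusted p = 0.0462), and 28 mitotic genes rose when adjusted over the list alone. Camera gave adjusted p = 1.80e-16 for this list, and adjusted p = 0.532 with an estimated correlation. Of 19 liver cancer and fetal liver markers (median 0.91), 3 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 1.42e-07, and adjusted p = 0.141 with an estimated correlation). They included Prom1, a progenitor marker, which rose from 0.654 ± 0.256 to 9.56 ± 5.45, and Afp, encoding alpha-fetoprotein, which rose from 1.46 ± 0.597 to 20.2 ± 23.0. When 1 library was left out, Prom1 passed in 8 of 12 fits, and Afp and Kif2c in 2 each. The 47 E2F target and DNA replication genes had a median of 0.43, with 0 up and 1 down both over all genes and adjusted over the list alone. The faller was Mcm10, a replication factor gene, from 32.1 ± 10.7 to 8.50 ± 4.39 (−1.85, adjusted p = 0.0319), against the direction of its list (camera adjusted p = 1.04e-04, and adjusted p = 0.72 with an estimated correlation). Mcm10 passed in only 6 of the 12 fits that left out 1 library. Of 20 p53 targets (median 0.22), 3 rose over all genes and 3 adjusted over the list alone, namely Btg2, Cdkn1a and the death receptor gene Tnfrsf10b. Cdkn1a, a cell cycle inhibitor gene, rose from 3.27 ± 2.43 to 16.6 ± 5.47 (camera adjusted p for the list = 0.0053, and adjusted p = 0.72 with an estimated correlation). The E2F target median was 0.28 without wild-type liver 1 and 0.22 without DKO tumor 2, and without DKO animals 1 and 2 it was 0.25 and the call was lost (adjusted p = 0.155). The p53 target median was 0.12 without DKO tumor 3. With the offset of 0.1 the medians were 1.37 for mitotic genes, 1.51 for liver cancer markers, 0.67 for E2F targets and 0.40 for p53 targets.

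Urea cycle, P450 and male-biased lists were lower in DKO tumors than in wild-type livers. All 26 urea cycle and amino acid catabolism genes had negative log2 changes (median −0.88). In this list 2 fell over all genes and 12 adjusted over the list alone (camera adjusted p = 1.95e-09, and adjusted p = 0.276 with an estimated correlation). Agxt, a glyoxylate enzyme gene, fell from 157 ± 67.5 to 53.4 ± 10.4 RPKM (−1.46, limma adjusted p = 0.0297), and the ornithine carrier gene Slc25a15 from 150.2 ± 10.2 to 81.7 ± 27.4 (−0.93, adjusted p = 0.0474). When 1 library was left out, Agxt passed in 7 of 12 fits and Slc25a15 in 2. Of 36 cytochrome P450 and phase I genes (median −0.45), 3 fell over all genes, and 6 fell and 1 rose adjusted over the list alone. Camera gave adjusted p = 0.0012, and adjusted p = 0.532 with an estimated correlation. Cyp2u1, which is also counted in the male-biased list, fell from 25.5 ± 7.96 to 4.29 ± 4.32, and Cyp2j5 from 196 ± 19.6 to 104 ± 18.3. Of 22 male-biased genes (median −1.60), 3 fell over all genes and 12 adjusted over the list alone (camera adjusted p = 2.41e-08, and adjusted p = 0.532 with an estimated correlation). Cyp2c54, which belongs to the P450 list, fell from 184 ± 53.2 to 36.3 ± 20.7. The male-biased list also holds Mup genes, whose copies are near-identical. Of 21 female-biased genes (median 0.63), 2 rose over all genes, and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.0024, and adjusted p = 0.532 with an estimated correlation). The 2 were Cyp2a4, whose reads can be shared with Cyp2a5, and Prom1, which is also counted in the liver cancer list. Apoa4, an apolipoprotein gene that belongs to the periportal list, rose from 249 ± 28.3 to 1684 ± 1192, against that list's median of −0.90. The female-biased median was 0.28 without DKO tumor 4. Without DKO animals 1 and 2 the P450 median was −0.13 and the male-biased median −1.02, and with quantile normalization the P450 call was lost (−0.13, adjusted p = 0.0916).

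Respiratory chain genes were also lower in DKO tumors than in wild-type livers. All 34 nuclear-encoded mitochondrial chain genes were negative (median −0.46; camera adjusted p = 6.97e-08, and adjusted p = 0.605 with an estimated correlation). The 20 bile acid genes (median −0.73, adjusted p = 0.0016), the 25 fatty acid oxidation genes (−0.45, 0.0017) and the 40 ribosomal protein genes (−0.33, 0.0017) were also lower, as were 22 lymphocyte markers (−0.24, 0.0376). The 16 cholangiocyte markers (0.33, 0.0127) were higher. With an estimated correlation, adjusted p was 0.532 for bile acid genes, 0.72 for fatty acid oxidation, ribosomal protein and cholangiocyte genes, and 0.762 for lymphocyte markers. None of these lists had a changed gene over all genes or adjusted over the list alone. The mitochondrial chain median was −0.19 with quantile normalization and −0.25 without DKO animals 1 and 2, and the lymphocyte median −0.56 with the offset of 0.1. Ribosomal protein genes have pseudogene copies, so their values are uncertain. Of 21 fatty acid synthesis genes (median 0.70, adjusted p = 0.0014), 1 rose over all genes and 4 adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). Of 20 immediate early and heat shock genes (0.58, adjusted p = 0.0014, and adjusted p = 0.532 with an estimated correlation), 3 rose over all genes, and 5 rose and 1 fell adjusted over the list alone. Among these, Atf3 rose from 1.30 ± 0.881 to 9.55 ± 6.31 RPKM and Fos from 0.411 ± 0.145 to 1.83 ± 0.405. The other was Btg2, which is also counted among the p53 targets. Of 20 unfolded protein response genes (0.26, adjusted p = 0.0153, and adjusted p = 0.72 with an estimated correlation), 1 rose over all genes and 2 adjusted over the list alone. The 1 was Atf3, already counted among the immediate early genes. Of 20 periportal genes (−0.90, adjusted p = 0.0153, and adjusted p = 0.72 with an estimated correlation), 2 rose and 1 fell over all genes, and 2 rose and 4 fell adjusted over the list alone. Cdh1, encoding E-cadherin, rose from 4.26 ± 1.92 to 32.3 ± 5.96. Of 16 clock genes (−0.76, adjusted p = 0.0409), 0 changed over all genes, and 2 rose and 8 fell adjusted over the list alone (adjusted p = 0.532 with an estimated correlation). Lists not called here but called in some of 24 other settings were endothelial (0.15 as reported, 6 settings), cholesterol (0.39, 4), acute-phase (−0.36, 4), hepatocyte protein (−0.12, 3), pericentral (0.46, 3), matrix (0.06, 2) and interferon genes (0.06, 1).

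Some of these list values against wild-type liver rested on single libraries. Without DKO tumor 4 the periportal median was −0.39 (camera adjusted p = 0.755), and only tumors 2 and 4 had a periportal mean below every wild-type liver. Within L03 the periportal median was −0.90 (0.0677). The fatty acid synthesis median was 0.42 without DKO tumor 4, the bile acid median −0.26 without DKO tumor 1, and the immediate early median 0.38 without wild-type liver 1. Without DKO tumor 3 the calls of fatty acid oxidation (−0.44, 0.054), cholangiocyte (0.26, 0.149) and clock genes (−0.87, 0.054) were lost. The clock call was also lost without wild-type liver 2 (−0.70, 0.0755), wild-type liver 4 (−0.68, 0.0778) or DKO liver 4 (−0.76, 0.084). Its median was much smaller in size without DKO animals 1 and 2 or with the Arntl covariate, as given below. The lymphocyte call was lost without wild-type liver 2 (−0.21, 0.0847), wild-type liver 3 (−0.14, 0.222), DKO liver 4 (−0.24, 0.0506), DKO tumor 2 (−0.18, 0.0912) or DKO tumor 4 (−0.11, 0.422), while the median was −0.14 without DKO tumor 1 and −0.46 without DKO tumor 3. Unfolded protein response genes lost their call without DKO tumor 2 (0.16, 0.0912), with the lane as a covariate (0.18, 0.0876) and within L03 (0.18, 0.0659).

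The remaining 14 lists were not called against wild-type liver. Median log2 changes were −0.12 for 29 hepatocyte secreted proteins and transcription factors (adjusted p = 0.348), 0.39 for 23 cholesterol biosynthesis genes (0.21) and 0.46 for 19 pericentral genes (0.22). They were −0.36 for 23 acute-phase genes (0.22), 0.06 for 28 interferon response genes (0.516), −0.06 for 25 macrophage and Kupffer cell markers (0.692) and 0.12 for 7 neutrophil markers (0.662). The 22 endothelial markers had a median of 0.15 (0.0801), 32 stellate cell, fibroblast and matrix genes 0.06 (0.593), 8 red blood cell genes 0.13 (0.692), and 4 adipocyte, pancreas and muscle genes −0.08 (0.692). The 22 WNT pathway and growth factor genes had a median of 0.29 (0.174). The 23 glutathione S-transferases and NRF2 targets had a median of −0.02 but a mean of 0.15 and an upward test (0.549), and 22 gluconeogenesis and glycolysis genes a median of 0.05, a mean of −0.12 and an upward test (0.903). In these lists 1 WNT gene rose over all genes. Adjusted over the list alone, 3 endothelial markers, 1 WNT gene and 1 acute-phase gene rose, 1 hepatocyte gene rose and 2 fell, and 1 red blood cell gene fell. With an exact permutation test on the mean of each list per library, the smallest adjusted p over the 33 lists was 0.086 here, 0.236 for DKO liver against wild-type liver, and 0.419 for DKO tumor against DKO liver. This test cannot give p below 0.029, so an adjusted p under 0.05 needs many lists at that limit at once. Unadjusted p was under 0.05, with groups that did not overlap, for 11 of the 33 lists here. The same held for 4 lists in DKO liver against wild-type liver and 2 in DKO tumor against DKO liver. The adjusted values therefore decide little.

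**Figure D2:**
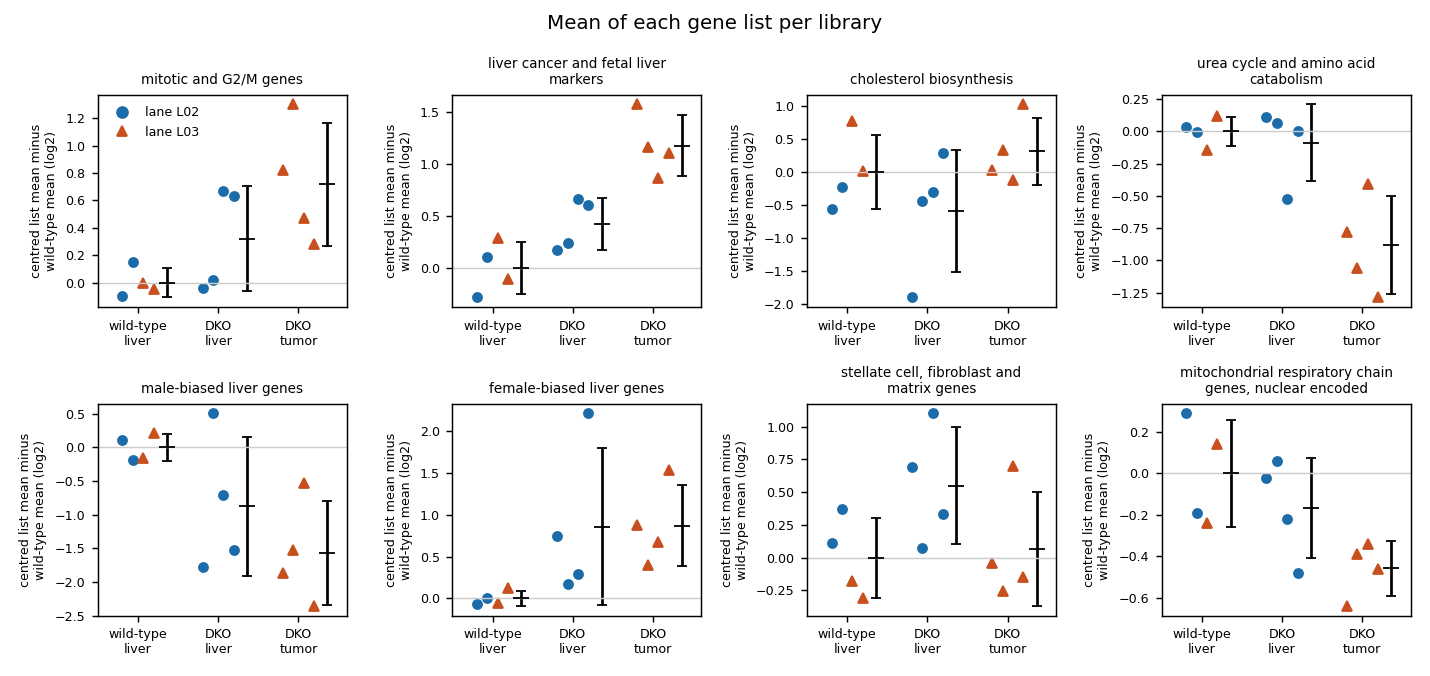
Mean log2(RPKM + 1) of 8 gene lists in each library, relative to the library's mean over all tested genes and to the wild-type mean, by group, with circles for L02, triangles for L03, and bars for mean ± SD (n = 4). Male-biased genes had a median log2 change of −1.60 in DKO tumors against wild-type livers, and mitotic genes of 0.72.

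DKO livers were compared with wild-type livers to find differences in liver outside the tumors. By their codes all 4 DKO livers came from animals with a tumor, so loss of E2f7 and E2f8 cannot be told apart from bearing a tumor. All of them also carry tag L02, whereas the wild-type livers carry both tags. Cyp2e1, a pericentral P450 gene, was at 2151 ± 1146 RPKM against 5246 ± 1181 (n = 4 each; log2 difference −1.51, limma adjusted p = 0.469). The bile acid and drug transporter gene Slco1b2 was at 262 ± 63.2 against 536 ± 37.5 (−1.07, adjusted p = 0.378). The heparan sulfate proteoglycan gene Sdc1 was at 96.5 ± 20.9 against 56.1 ± 8.17 (0.76, adjusted p = 0.264). None of the 11351 genes passed adjustment with limma.

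The smallest adjusted p was 0.076 for the tubulin gene Tubb2a, chosen after its values were seen, at 33.4 RPKM in DKO livers and 8.10 in wild-type livers (log2 difference 1.89, SE 0.29). At an unadjusted p under 0.05 there were 1408 genes (12.4%), where 568 would be expected with no differences, and groups did not overlap for 861 genes (7.6%, where chance gives 2.9%). Voom on the recovered reads, a lane covariate, and the L02 libraries alone (4 against 2) each gave 0 genes. Median-of-ratios scaling gave 1. Leaving out DKO liver 4 gave 2 genes, leaving out wild-type liver 1, 2 or 3, DKO liver 1 or DKO tumor 3 gave 1 each, and leaving out any other library gave 0.

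Among gene lists in DKO liver against wild-type liver, camera called 18 of 33, 10 up and 8 down. No list had a changed gene over all genes. With an estimated correlation none of the 18 was called, and adjusted p = 0.605 with an estimated correlation was found for each higher list except lymphocyte markers. All 32 stellate cell, fibroblast and matrix genes were positive (median 0.64, adjusted p = 8.57e-06), among them Fn1, encoding fibronectin, at 211 ± 66.2 against 167 ± 26.7 RPKM. All 36 mitotic genes were positive (0.43, 8.57e-06), among them cyclin A2, Ccna2, at 3.37 ± 1.93 against 1.55 ± 0.419. Macrophage and Kupffer cell markers were positive in 24 of 25 (0.69, 7.04e-04), and the Kupffer cell lectin gene Clec4f was at 108 ± 37.9 against 59.3 ± 29.5. Endothelial markers (0.55, 1.33e-04; 21 of 22 positive) included the water channel gene Aqp1 at 55.4 ± 5.15 against 36.7 ± 8.63. All 7 neutrophil markers were positive (1.47, 1.33e-04), with S100a8 at 18.1 ± 19 against 3.75 ± 2.11. Cholangiocyte markers (0.41, 0.0028; 15 of 16), gluconeogenesis and glycolysis (0.35, 0.0244; 17 of 22) and female-biased genes (1.05, 0.0199; 17 of 21) were higher. Immediate early and heat shock genes (0.51, 1.36e-04; 19 of 20) were also higher. Lymphocyte markers were positive in 21 of 22 (0.38, 0.0018, and adjusted p = 0.618 with an estimated correlation). Adjusted over the list alone, 3 neutrophil markers, 3 immediate early genes, 2 female-biased genes, 2 lymphocyte markers and 1 cholangiocyte marker rose, with 0 falling and 0 changed in the other lists named so far. With the offset of 0.1 the medians were 0.91 for mitotic, 0.66 for lymphocyte and 0.70 for cholangiocyte genes.

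Several of these higher values in DKO livers depended on lane or on 1 library. The matrix median was 0.37 with the lane as a covariate (camera adjusted p = 0.0215), 0.37 within L02 (0.0096) and 0.41 without DKO liver 3. Without DKO liver 3 the medians were also 0.22 for mitotic genes, 0.18 for lymphocyte markers, 0.84 for neutrophil markers and 0.20 for cholangiocyte markers. Female-biased genes had list means of 0.35, −0.23, −0.11 and 1.81 in DKO livers 1 to 4, relative to all tested genes. Without DKO liver 4 their median was 0.34 and the call was lost (0.854), as it was without wild-type liver 3 (1.12, 0.0559). The gluconeogenesis call was lost without wild-type liver 3 (0.27, 0.0522), wild-type liver 4 (0.25, 0.0517) or DKO liver 2 (0.34, 0.0792), with the lane as a covariate (0.19, 0.229) and within L02 (0.19, 0.274).

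Lower lists in DKO livers were led by male-biased genes, negative in 19 of 22 (median −0.80, adjusted p = 8.57e-06). Adjusted p = 0.605 with an estimated correlation was found for each lower list except pericentral and mitochondrial chain genes. Fatty acid oxidation genes were negative in 22 of 25 (−0.35, 8.57e-06), cholesterol biosynthesis in 21 of 23 (−0.51, 1.66e-05), bile acid genes in 17 of 20 (−0.31, 7.58e-05) and P450 genes in 23 of 36 (−0.45, 8.95e-05). The P450 gene Cyp3a11, which has close paralogs, was at 863 ± 538 against 1886 ± 232 RPKM. Clock genes had a median of −0.28 (0.0459). Pericentral genes (−0.39, 0.0031; 16 of 19 negative) included Oat, an ornithine enzyme gene, at 182 ± 42.3 against 411 ± 72.5, and had adjusted p = 0.662 with an estimated correlation. Mitochondrial chain genes (−0.06, 0.0199) had adjusted p = 0.783 with an estimated correlation. Adjusted over the list alone, 2 clock genes rose and 4 fell, and 0 changed in the other lower lists. Among lists not called, the E2F target list had a median of 0.24 with 41 of 47 positive (0.281), with Rrm2, a nucleotide synthesis gene, at 9.31 ± 7.60 against 3.79 ± 1.5. It was called in 4 of 24 other settings, namely without DKO animals 1 and 2 (0.66, adjusted p = 1.17e-07), wild-type liver 2 (0.40, 0.0151), DKO liver 1 (0.35, 0.0067) or DKO liver 2 (0.40, 0.0198), and its median was −0.03 without DKO liver 3. Liver cancer markers (0.47, 0.0678) were called in 12 settings, among them the lane covariate (0.58, 0.0048) and the omission of animals 1 and 2 (0.70, 0.0114). Other lists called in some settings were interferon response (0.40 as reported, 7 settings), glutathione S-transferases (−0.12, 6), ribosomal proteins (−0.01, 5), p53 targets (0.19, 3), hepatocyte proteins (0.03, 2), urea cycle (−0.06, 2), acute-phase (0.22, 2), fatty acid synthesis (0.15, 1) and periportal genes (0.09, 1). In the settings that called them, medians were negative for hepatocyte proteins (−0.22 and −0.17), acute-phase genes (−0.07 and −0.13) and periportal genes (−0.25). Median, mean and test differed in sign for hepatocyte (0.03, 0.06, down), periportal (0.09, 0.18, down), acute-phase (0.22, 0.05, down), red blood cell (0.14, 0.09, down), adipocyte (0.01, −0.22, down) and WNT lists (−0.01, 0.16, down).

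Lower values in DKO livers also depended on lane, on 1 library or on other settings. With quantile normalization the P450 and pericentral calls were lost, as given below. The cholesterol median was 0.00 with the lane as a covariate (camera adjusted p = 0.0301) and 0.00 within L02 (0.0277). It was −0.06 without wild-type liver 3 (0.0027), and −0.05 without DKO liver 1, where the call was lost (0.0875). The cholesterol median turned to 0.24 with the Arntl covariate and to 0.21 without DKO animals 1 and 2. The fatty acid oxidation median was −0.08 without DKO liver 4, the male-biased median −0.49 without DKO liver 1, and the bile acid median −0.47 without wild-type liver 2 and −0.49 without DKO liver 3. The clock call was lost without wild-type liver 2 (−0.19, 0.103), wild-type liver 4 (−0.24, 0.0906), DKO liver 1 (−0.25, 0.0711) or DKO liver 3 (−0.41, 0.106), and with the lane as a covariate (−0.18, 0.053). Its median was −0.16 without DKO liver 2 (0.0496). The mitochondrial chain call was lost without wild-type liver 1 (0.00, 0.41), wild-type liver 4 (−0.05, 0.0906), DKO liver 3 (−0.11, 0.0645) or DKO liver 4 (0.10, 0.465). Its median was −0.19 without wild-type liver 2, −0.12 without wild-type liver 3, −0.10 without DKO liver 1 and −0.15 without DKO liver 2.

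DKO tumors were compared with DKO livers, which come from the same animals by their codes, to ask what separates tumor from surrounding liver. The kinesin gene Kif5c (chromosome 2, 49474833 to 49630297) rose from 0.10, 0.23, 0.12 and 0.27 RPKM in the DKO livers to 2.98, 2.69, 1.75 and 2.43 in the tumors. Its log2 change was 1.54 (SE 0.14, limma adjusted p = 4.34e-04), and with the animal as a block 1.54 (SE 0.15, adjusted p = 0.0047). It was the only one of 11351 genes to pass in the 12-library fit and was named after its values were seen, being below the level the rule requires. Wild-type livers had 0.02, 0.07, 0.23 and 0.08 RPKM.

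With the animal as a block, 71 genes passed, 35 up and 36 down, each named one in 4 of 4 animals. Gp2, an epithelial surface glycoprotein gene (chromosome 7, 126586057 to 126602785), was at 13.0 ± 2.46 RPKM in tumors against 0.036 ± 0.025 in DKO livers (log2 change 3.75, SE 0.17, limma adjusted p = 2.55e-04). The keratin gene Krt20 was at 8.24 ± 2.02 against 0.13 ± 0.195 (3.02, adjusted p = 2.77e-04), and the lymphoid transcription factor gene Spib at 9.73 ± 0.875 against 0.661 ± 0.467 (2.73, adjusted p = 6.06e-04). The chemokine gene Ccl20 was at 8.30 ± 2.34 against 0.233 ± 0.212 (2.89, adjusted p = 0.0014). The growth factor gene Igf2 (chromosome 7, 149836672 to 149845393) was at 0.52 ± 0.527 against 9.66 ± 2.20 (−2.85, adjusted p = 0.001). The WNT modulator gene Sfrp2 was at 0.145 ± 0.109 against 5.13 ± 1.46 (−2.39, adjusted p = 0.0025). The matrix gene Postn was at 2.23 ± 1.11 against 10.1 ± 3.88 (−1.77, adjusted p = 0.0134), and the collagen gene Col1a2 at 4.49 ± 2.36 against 15.0 ± 6.0 (−1.56, adjusted p = 0.0113).

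All DKO tumors carry tag L03 and all DKO livers L02, so neither lane alone holds both groups. For that reason the lane term of every fit with the lane as a covariate was estimated from the 4 wild-type livers alone, 2 of each tag. The wild-type livers of L03 differed from those of L02 in the same direction as tumor from DKO liver for 68 of the 71 genes, by a median of 0.93 of the tumor difference. Gp2 was at 14.5 and 10.1 RPKM in the L03 wild-type livers, and at 0 and 0.04 in the L02 ones. With lane as a covariate over 12 libraries, 0 genes passed with limma, and Kif5c had a log2 change of 1.40 (SE 0.25, adjusted p = 1). With the animal as a block, 1954 genes had an unadjusted p under 0.05, and 1822 did in the 12-library fit. Groups did not overlap for 704 genes (6.2%, where chance gives 2.9%). In the 12-library fit the count was 363 without DKO tumor 3, 31 without wild-type liver 3, 20 without DKO liver 3, 3 without wild-type liver 1, and 2 without wild-type liver 2 or wild-type liver 4. The mean log2 size factor of tumors minus that of DKO livers was −0.134, so dividing by these factors (median-of-ratios scaling) moves log2 changes up by that amount, and the camera tests of lists are relative to the other genes.

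**Figure D3:**
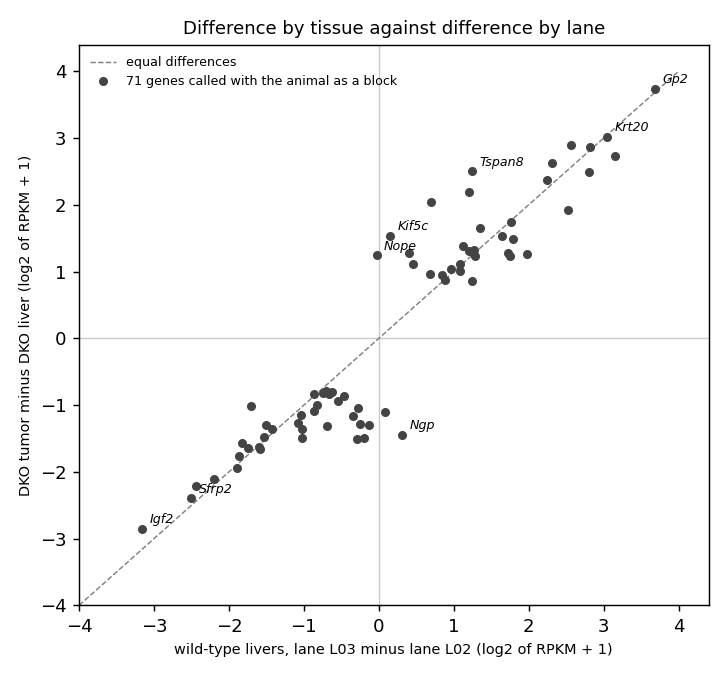
For the 71 genes called between DKO tumors and DKO livers of the same animals, the log2 difference of wild-type livers tagged L03 minus L02 (horizontal) against DKO tumor minus DKO liver (vertical), 1 point per gene, with a dashed line of equality. Of the 71 points, 68 have the same sign on both axes.

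Liver cancer and cholesterol lists had higher means, and lymphocyte and macrophage lists lower means, in the DKO tumor than in the DKO liver of 4 of 4 animals, although cholesterol did not hold with the lane as a covariate. Camera called 18 lists, 8 up and 10 down, with 0 changed genes over all genes in any list, and 19 lists with the animal as a block. With an estimated correlation none was called in either fit. Of 19 liver cancer markers (median 0.65, camera adjusted p = 9.12e-06, and adjusted p = 0.32 with an estimated correlation; with lane 0.41), 3 rose and 1 fell adjusted over the list alone, and 10 rose and 1 fell with the block. The trefoil factor gene Tff3 was at 140 ± 97.9 RPKM in tumors against 41.5 ± 43.5 in DKO livers. Without DKO animals 1 and 2 the liver cancer median was 0.34 and the call was lost (0.329). Of 23 cholesterol biosynthesis genes, 22 were positive (0.87, 8.33e-08, and adjusted p = 0.793 with an estimated correlation), with Sc5d, a sterol desaturase gene, at 312 ± 108 against 164 ± 67.4. Their median was −0.10 with lane as a covariate (0.181), 0.30 without DKO liver 1 and 0.43 without DKO tumor 4. Fatty acid synthesis genes were positive in 15 of 21 (0.58, 1.24e-04, and adjusted p = 0.793 with an estimated correlation). Their median was 0.37 with lane and 0.29 without DKO liver 1.

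Mitotic and E2F target lists were higher in the tumor than in the liver of DKO animals 1 and 2 and lower in those of animals 3 and 4. Over all animals 33 of 36 mitotic genes were positive (median 0.28, camera adjusted p = 2.09e-07; with lane 0.29), and 36 of 47 E2F targets (0.24, 7.44e-04; with lane 0.28). With an estimated correlation, adjusted p was 0.793 for mitotic genes and 0.823 for E2F targets. Without animals 1 and 2 the medians were −0.22 for mitotic genes and −0.36 for E2F targets, called in the other direction (2.05e-07 each). The mitotic median was 0.18 without DKO liver 1, 0.14 without DKO liver 2, 0.50 without DKO liver 3 and 0.12 without DKO tumor 2. The E2F target call was lost without DKO liver 1 (0.07, 0.0573), DKO liver 2 (0.06, 0.0575) or DKO tumor 2 (0.02, 0.33), and the median was 0.44 without DKO liver 3. With the offset of 0.1 the medians were 0.54 for mitotic genes and 0.37 for E2F targets. Pericentral genes were positive in 17 of 19 (0.58, 4.02e-05, and adjusted p = 0.793 with an estimated correlation; with lane 0.72), but their mean was higher in tumor than in liver in 2 of 4 animals, and lower in 1. Their median was 1.38 without DKO tumor 1, and 0.03 without DKO tumor 4, where the call was lost (0.0667). Glutathione S-transferases and NRF2 targets were positive in 15 of 23 (0.10, 0.0281, and adjusted p = 0.793 with an estimated correlation; with lane 0.43), with a median of −0.13 (0.399) without DKO liver 4 and −0.06 (0.127) without DKO tumor 4. Their median was 0.22, 0.23 and 0.39 without DKO livers 1, 2 and 3, and 0.38 and 0.19 without DKO tumors 1 and 2. Unfolded protein response genes were positive in 15 of 20 (0.14, 0.0094, and adjusted p = 0.793 with an estimated correlation; with lane −0.13). Their call was lost without DKO liver 1 (0.02, 0.127) or DKO tumor 2 (0.06, 0.073), and the median was 0.26 without DKO tumor 1 and 0.07 without DKO tumor 4.

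Adjusted over the list alone, 1 fatty acid synthesis gene rose and 1 fell, and 9 cholesterol genes rose with the block. With the block, changed genes over all genes were 5 matrix genes, 3 neutrophil markers, 1 gluconeogenesis gene and 1 liver cancer marker that fell. Tacstd1, which is in both the liver cancer and the cholangiocyte list, rose. Most of these genes followed the lane tag among wild-type livers. The wild-type L03 minus L02 difference was 1.16 of the tumor difference for Col1a2, 1.06 for Col6a1, 1.04 for Col6a2 and 0.96 for Mmp2. It was 0.98 for Mmp9, 0.80 for Gapdh, 1.11 for Igf2 and 1.41 for Tacstd1 (now Epcam). It was 0.19 for Lrat, 0.13 for S100a8 and −0.21 for Ngp.

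Lymphocyte markers were negative in 22 of 22 (median −0.62, camera adjusted p = 5.91e-07; with lane −0.71), with 8 down adjusted over the list alone and 18 with the block. Adjusted p = 0.793 with an estimated correlation was found for lymphocyte, macrophage, neutrophil and matrix genes alike. The lymphocyte median was −1.41 with the offset of 0.1. Macrophage and Kupffer cell markers were negative in 22 of 25 (−0.66, 0.0012; with lane −0.96), with 1 up and 8 down adjusted over the list alone. Clec4f was at 29.4 ± 35.3 RPKM in tumors against 108 ± 37.9 in DKO livers. The macrophage median was −0.40 without DKO liver 3 and −1.14 without DKO tumor 3. Neutrophil markers (−1.44, 0.0028; with lane −1.09, adjusted p = 0.19), with 1 down adjusted over the list alone, included S100a8 at 5.43 ± 6.28 against 18.1 ± 19. Matrix genes were negative in 27 of 32 (−0.63, 0.0012; with lane −0.02, 0.264), with 6 down adjusted over the list alone. With the block 5 matrix genes fell over all genes, most of them with a lane difference of like size among wild-type livers. Adjusted over the list alone, 19 matrix genes fell and 1 rose with the block. Without DKO liver 3 the medians were −0.73 for neutrophil and −0.36 for matrix genes.

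Urea cycle and amino acid catabolism genes were negative in 25 of 26 (median −0.82, camera adjusted p = 1.36e-07, and adjusted p = 0.458 with an estimated correlation; with lane −0.66), with 9 down adjusted over the list alone. Cps1, the first urea cycle enzyme gene, was at 521 ± 337 RPKM in tumors against 766 ± 75.2 in DKO livers, and Arg1, the arginase gene, at 675 ± 470 against 1184 ± 187. The list mean was lower in the tumor of 3 of 4 animals, and the median was −0.27 without animals 1 and 2. Mitochondrial chain genes were negative in 33 of 34 (−0.44, 1.63e-04, and adjusted p = 0.793 with an estimated correlation; with lane −0.34), with 2 down adjusted over the list alone. Their median was −0.18 with quantile normalization, −0.29 without DKO tumor 1, and −0.03 without animals 1 and 2, where the call was lost (0.482). Male-biased genes were negative in 22 of 22 (−0.66, 0.0094, and adjusted p = 0.793 with an estimated correlation; with lane −0.85), with 2 down adjusted over the list alone. Without animals 1 and 2 the male-biased median was −0.32 and without DKO tumor 3 it was −1.12, and the call was lost without DKO liver 2 (−0.28, 0.627) or DKO tumor 4 (−0.44, 0.318).

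Periportal genes (median −0.83, camera adjusted p = 0.0226, and adjusted p = 0.793 with an estimated correlation; with lane −0.96, 0.0535) had 2 up and 8 down adjusted over the list alone, and a lower mean in the tumor of 2 of 4 animals. Their call was lost without DKO liver 2 (−0.88, 0.0575), DKO liver 4 (−0.90, 0.257) or DKO tumor 4 (−0.47, 0.698). Gluconeogenesis and glycolysis (−0.29, 0.0429; with lane −0.14, 0.856) and ribosomal proteins (−0.34, 0.025; with lane −0.17, 0.745) had 0 changed genes adjusted over the list alone. With an estimated correlation, adjusted p was 0.793 for the first and 0.824 for the second. With the block, 2 genes of each of these lists fell adjusted over the list alone. The gluconeogenesis call was lost without DKO liver 1 (−0.26, 0.067), DKO liver 2 (−0.28, 0.0911), DKO tumor 2 (−0.23, 0.073) or DKO tumor 4 (−0.34, 0.127), and the median was −0.19 without DKO liver 3. The ribosomal call was lost without DKO liver 1 (−0.21, 0.474), DKO liver 3 (−0.22, 0.075) or DKO tumor 3 (−0.35, 0.231), and the median was −0.53 without DKO liver 4.

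With the animal as a block, acute-phase genes were also called (−0.62, camera adjusted p = 0.0249, and adjusted p = 0.727 with an estimated correlation), whereas all 12 libraries gave 0.312. Median, mean and test differed in sign in the 12-library fit for bile acid (−0.06, −0.20, up), fatty acid oxidation (−0.09, −0.04, up), female-biased (−0.13, −0.09, up), cholangiocyte (−0.18, −0.11, up), red blood cell (−0.02, −0.08, up), adipocyte (−0.09, 0.08, up) and immediate early lists (0.04, −0.01, up). None of those was called. Of the lists not called in the 12-library fit, 8 were called at least once in 24 other settings, the block included, namely acute-phase (6 settings), WNT (5), p53 targets (3), fatty acid oxidation (2), endothelial, interferon, female-biased and P450 lists (1 each). Without animals 1 and 2 the P450 median went from −0.26 to 0.32 (adjusted p = 0.0053). The fatty acid oxidation median went from −0.09 to 0.11 with the lane as a covariate and to 0.25 without animals 1 and 2. Without DKO liver 4 the female-biased median went from −0.13 to 0.35 and the WNT median from 0.14 to −0.05.

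The genes changed in DKO liver and in DKO tumor, each against wild-type liver, had an overlap of 0, because limma called 0 in DKO liver. The log2 changes of all tested genes correlated at 0.52 between these comparisons, which share their wild-type livers and whose DKO livers and tumors came from the same animals, across genes that are not independent replicates. Simulated unchanged groups, which left out the shared animals, gave a mean correlation of 0.50. The covariance was 0.084, against 0.036 in the simulated groups. When the wild-type livers were divided 2 and 2 between the comparisons, the 6 ways gave correlations of 0.15 to 0.56, covariances of 0.031 to 0.089, and an overlap of 0 in each. In a principal component analysis, the first 3 components held 28.2, 20.6 and 14.5% of the variance.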

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

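The tests of lane and tumor state for the genes separating tumors from livers, of lane for Kif5c, of lists under swaps within animals, of tumor state and E2f7/E2f8 loss for clock genes, and of female animals and hepatocyte share for male-biased genes were chosen after the results were seen, while the others were set before.

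Among 111 groups of 4 libraries, 102 for 34 named genes and 9 for read totals and read shares, 4 held a library far from the other 3, where chance gives about 1 in 20, or 6. Cyp2a4 was at 9.64 RPKM in DKO liver 1 and at 97.94 to 122.22 in the other DKO livers. Gldn was at 1.79 in wild-type liver 3 and at 0.32 to 0.37 in the others. Krt20 was at 0.42 in DKO liver 3 and at 0 to 0.06 in the others. Mup1 was at 3.85 in DKO tumor 3 and at 0.77 to 0.88 in the others, with reads shared among its copies.

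Genes separating DKO tumors from DKO livers of the same animals followed the lane tag, also among wild-type livers. The median ratio of the wild-type L03 minus L02 difference to the tumor difference was 0.93, so a difference between lanes may account for most of the 71 genes, and both L03 wild-type livers lay apart from both L02 ones in the direction of the tumors for 62, which argues against tumor state as their cause. The ratio was 0.19 or less for 8 genes (Kif5c, Fermt3, S100a8, Ngfr, Lrat, and Ngp, Nope and Lrrc25, which moved the other way), and for Kif5c a wild-type difference of 0.15 on the log2(RPKM + 1) scale argues against the lane on that scale. The offset compresses low values. Kif5c was at 0.16 RPKM in L03 and 0.04 in L02 wild-type livers, against 2.46 in tumors and 0.18 in DKO livers. As a fold change the wild-type difference is not small, but it rests on values near the floor. As a source of the lane difference, placental RNA or reads were tested on 4 genes only. Of these 0% were higher in every L02 library, which met the bound set before against this source. The 4 genes (Mest, Pcdh12, Phlda2 and Afp) were detected in wild-type livers of both tags, so this share cannot decide. The other 29 placental genes in the data were below the filter, at 0.41 RPKM or less in every library. Those values, read afterwards, give no sign of placental RNA. Intestinal RNA or reads in L03 (7.4% of 27 genes) and embryonic mesenchyme in L02 (13.3% of 15 genes) stay open because these shares lie between the bounds set before and the lists left out genes already seen, although Vil1 was lower in every L03 library and Agr2, Cdx1 and Cdx2 were at 0 in every library, values read afterwards that go against intestinal epithelium as a whole.

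Clock genes differed in DKO animals 1 and 2, with Arntl, encoding the clock activator BMAL1, at 11.2 and 9.95 RPKM in their livers and 9.24 and 10.9 in their tumors, against 0.48 to 1.6 in wild-type livers. Liver and tumor of the same animal correlated at 0.88 over 16 clock genes, the highest of 24 pairings of livers with tumors (next 0.82), which argues against tumor state. In 1 animal both tissues lay within 1 wild-type SD of the wild-type range of Arntl, which argues against E2f7/E2f8 loss as the whole cause. Time of day was argued against in the form tested, since 3 of 12 values of Usp2, Wee1 and Tspan4 lay below every wild-type liver, but wild-type liver 1 set the lowest values of all of these genes, and 9 of 12 lay below the other 3 wild-type livers, a count made afterwards. Sampling times are not given in the sources used here, so time of day in another form remains possible and untested.

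Male-biased genes were lower in DKO tumors than in wild-type livers by a median of −1.60 on the log2 scale. Female animals among the DKO mice are argued against, because the Y-linked gene Ddx3y was at 11.01 RPKM or more in all 8 DKO libraries and at 14.4 to 21.94 in wild-type livers. A lower share of hepatocytes is argued against by a median of −0.12 for hepatocyte proteins, and the lane by a median of −1.57 with the lane as a covariate. Of 22 genes, 19, 1, 10 and 19 lay below every wild-type liver in DKO livers 1 to 4, and 17, 16, 11 and 21 in DKO tumors 1 to 4. Hormone state, genotype and tumor state stay open and were not tested.

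Other splits of the same 8 libraries into 4 and 4, 35 in each comparison, were fitted to see whether chance can be excluded. For DKO liver against wild-type liver, the real count of genes was 0, which all 35 splits must reach (highest other 2), so the splits say nothing about it. For its lists, 10 splits gave as many (real 18, highest other 23), so chance cannot be excluded. For DKO tumor against DKO liver, 6 gave as many genes (real 1, highest other 90) and 11 as many lists (18, highest other 22), so chance cannot be excluded for the fit without the block, whose splits ignored the pairs of tumor and liver. The split with 90 genes set tumors 1, 2 and 4 with DKO liver 4 against the rest, which points to a structure of the samples. For DKO tumor against wild-type liver, 1 split, the real one, gave 216 genes (highest other 1). This is the smallest share that 35 splits can give, and the tests of splits were not adjusted. Chance is therefore less likely for this count but is not excluded. As many lists were given by 3 splits (19, highest other 22), so chance is not excluded for lists. Within animals, 1 of 8 swaps of tumor and liver, the real one, gave 71 genes (highest other 0), and 2 of 8 gave as many lists (real 19, highest other 21), but 8 swaps are too few for a share under 0.05.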

How the results depend on the processing

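Quantile normalization, voom, the other transcript per gene, the Arntl covariate, omission of DKO animals 1 and 2, scaling combined with the block, omission of lane-following genes and the single-lane fits were chosen after seeing the data. The planned count-model alternative (a Wald test on counts) was not run because the values are RPKM. The alternative with library size only equals the values as deposited. Unless a reason is given, the cause was not tested.

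For DKO liver against wild-type liver the count of 0 genes became 1 with median-of-ratios scaling, 1 with the 8 libraries alone, 2 with the Arntl covariate and 1 without animals 1 and 2. It was 0 to 2 when 1 library was left out. For DKO tumor against DKO liver, the count of 1 became 55 with the 8 libraries alone, 0 with the lane covariate, 71 with the block, 24 with quantile normalization, 0 without animals 1 and 2 (fewer samples), and 46 with scaling and block. It was 76 with voom and a random animal effect, 0 with that and the lane, and 2 with the block after lane-following genes were removed (6559 genes left). Of the 71 genes, 58 were removed in this way. The p-values were then adjusted again over the genes left, so more than 2 of the 71 did not follow the lane. Leaving out 1 library gave 1 to 363.

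For DKO tumor against wild-type liver the count of 216 became 609 with median-of-ratios scaling (359 up and 250 down, 215 shared with the 216), 478 with quantile normalization (198 shared) and 112 without a filter (105 shared). It became 3 with the lane covariate, where the median change went from 1.18 (SE 0.24) to 1.12 (SE 0.30), so that the larger error ended most calls. It became 128 with a block by replicate number, which names different animals here, 10 without animals 1 and 2 (fewer samples) and 25 within L03 (fewer samples). Leaving out 1 library gave 16 to 413. Other settings gave 196 (voom) to 303 (8 libraries alone), with 239 for the Arntl covariate, of which 111 were shared.

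Lists called fell from 18, 18 and 19 to 0, 0 and 0 with an estimated correlation, which was as high as 0.819 against the preset 0.01. Leaving out 1 library gave 15 to 23, 14 to 20 and 17 to 22, and 13, 10 and 13 lists passed in every such fit. In DKO liver against wild-type liver, the mitochondrial chain median was −0.01 with quantile normalization (adjusted p = 0.926) and 0.10 without DKO liver 4 (0.465), with −0.19 as the lowest value when 1 library was left out. Cholesterol biosynthesis became 0.24 (0.307) and clock genes 0.07 (0.133) with the Arntl covariate, and cholesterol 0.21 (0.488) without animals 1 and 2. In DKO tumor against DKO liver the lane covariate gave −0.10 for cholesterol (0.181), −0.02 for matrix (0.264) and −0.13 for unfolded protein response genes (0.428). Without animals 1 and 2, E2F targets were at −0.36 (2.05e-07) and mitotic genes at −0.22 (2.05e-07). Glutathione S-transferases were at −0.13 (0.399) without DKO liver 4 and −0.06 (0.127) without DKO tumor 4, with 0.39 as the highest value when 1 library was left out.

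Other settings ended further list calls. Further lost calls are given beside their values. In DKO liver against wild-type liver, quantile normalization gave P450 −0.34 (0.102), pericentral −0.42 (0.074) and clock genes −0.31 (0.177). Gluconeogenesis was at 0.28 (0.398) with the Arntl covariate and 0.16 (0.314) without animals 1 and 2, and female-biased genes at 0.70 (0.176) without a filter. Clock genes gave 0.139 with median-of-ratios scaling, 0.0679 without a filter, 0.173 with the stricter filter, and 0.0624 with the offset of 0.1 or without animals 1 and 2. In DKO tumor against DKO liver, glutathione S-transferases gave 0.117 with scaling, 0.102 with scaling and block, and 0.161 without a filter. Gluconeogenesis gave 0.0752 with scaling and 0.176 with quantile normalization. Without animals 1 and 2, gluconeogenesis was at −0.08 (0.108), ribosomal proteins at −0.10 (0.142) and unfolded protein response genes at 0.09 (0.565). In DKO tumor against wild-type liver, omitting animals 1 and 2 gave lymphocyte markers −0.01 (0.0695) and unfolded protein response genes 0.23 (0.0947). Quantile normalization gave bile acid −0.33 (0.147), fatty acid oxidation −0.18 (0.161) and periportal genes −0.67 (0.16). Lymphocyte markers gave 0.0662 with the stricter filter and 0.12 with the Arntl covariate. Clock genes gave 0.0647 without a filter, 0.22 with the stricter one, 0.0795 with the 8 libraries alone and 0.0632 with the offset of 0.1.

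Other calls held with medians over 1.5 times apart (those for the offset of 0.1 and gained calls are in the report). In DKO liver against wild-type liver, medians without animals 1 and 2 were 0.79 for mitotic, −0.72 for P450, −0.60 for bile acid, −0.54 for fatty acid oxidation, 0.64 for cholangiocyte and −0.25 for mitochondrial genes. Quantile normalization gave mitotic 0.28 and lymphocyte 0.23, the Arntl covariate pericentral −0.11, cholangiocyte 0.62 and mitochondrial −0.11, the lane covariate mitochondrial −0.11, scaling mitochondrial −0.16, and no filter neutrophil 0.83. In DKO tumor against DKO liver, omitting animals 1 and 2 gave glutathione S-transferases 0.64, pericentral 1.36 and cholesterol 0.50. Quantile normalization gave glutathione S-transferases 0.37, ribosomal −0.22 and unfolded protein response 0.29, scaling the last 0.26, and no filter liver cancer 0.42 and neutrophil −0.59. In DKO tumor against wild-type liver, omitting animals 1 and 2 gave p53 0.35, bile acid −0.22, ribosomal −0.20 and clock −0.26, and quantile normalization p53 0.14, urea cycle −0.58, ribosomal −0.21 and unfolded protein response 0.51. The Arntl covariate gave p53 0.38, bile acid −0.44, fatty acid synthesis 1.14, female-biased 1.11, cholangiocyte 0.64 and clock −0.23, no filter female-biased 0.37 and cholangiocyte 0.14, no filter or the stricter one immediate early 0.38, and the lane covariate cholangiocyte 0.21.

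At 7.985 to 15.956 M reads, E2f7 had 3 to 22 reads per library, so its differences rest on few reads.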

Other observations

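Genes and samples in this part were chosen after their values were seen, no test was run on them, and no explanation is offered. Genes of the pericentral list differed widely among the 4 DKO tumors, with list means of 0.52, 2.88, 1.26 and 3.75 relative to all tested genes. Means of the WNT pathway and growth factor list were 0.10, 0.71, 0.48 and 0.71. Glul, encoding glutamine synthetase, was at 53.2, 942, 167 and 2502 RPKM in tumors 1 to 4, and at 110 to 235 in the 8 livers. Axin2 was at 0.53, 10.3, 1.59 and 10.6, and Lgr5 at 0.13, 4.28, 0.55 and 5.14. Notum was at 2.47, 39.9, 6.53 and 30.3, Rhbg at 2.69, 40.8, 3.88 and 80.8, and Slc1a2 at 8.11, 111, 18.8 and 125. Tbx3 was at 0.84, 6.79, 1.78 and 18.8. In tumor 4 the periportal genes Cyp2f2 and Hal were at 48.1 and 6.76.

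Kupffer cell genes also varied among tumors 1 to 4. Clec4f was at 13.5, 20.4, 81.2 and 2.63 RPKM, Vsig4 at 14.4, 16.8, 44.5 and 2.18, and Cd5l at 21.1, 17.6, 54.2 and 3.04. Afp was at 10.8, 13.0, 3.05 and 54.1. DKO liver 3 had the neutrophil genes S100a8 at 46.0, S100a9 at 57.2, Ngp at 26.0 and Camp at 11.9. Sult3a1 was at 292 in the liver and 435 in the tumor of DKO animal 4, and Gpc3 at 17.0 and 8.79 in those of animal 3.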
